A study of Mus musculus with 20 samples.

How the data were processed

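Retinas of Nrl knockout mice on the C57Bl/6J background were profiled on Affymetrix exon arrays at 5 ages, 1, 2, 4, 6 and 10 months, with 4 mice per age. Per the labels, total RNA was depleted of ribosomal RNA and amplified as sense-strand cDNA before hybridisation, and both retinas of a mouse made up a sample, so the replicates are separate mice. The deposited values are log2 intensities per exon-level probe set, made by the authors with RMA (robust multi-array average: background correction, normalization between arrays and summary of probes) per the submitters' processing notes. The software version and how probe sets were selected are not given in the sources used here. The table held 194293 probe sets on 20 arrays with values from 0.986 to 14.3 and no missing value. For arrays, precision is limited by their number, 4 per age. Since RMA gives the arrays a common distribution, a shift of all genes at an age would not be seen.

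Probe sets were named through the platform's gene table. Of all probe sets, 179496 had 1 gene symbol, 1328 had several and were left out, and 13469 had none there and were left unnamed. Symbols were brought up to date through the synonyms of the RefSeq gene table of GRCm38.p6, which changed the names of 2014 symbols. Of the 15803 genes, 15741 names are current in that table and 62 were kept as given for the array. Values were summarised per gene and array by median polish over a median of 9 probe sets, and 807 genes had 1 probe set. Genes in the lowest 25% of mean level over the 20 arrays (log2 under 5.61) were left out, which left 11852. No coordinates are given, since the build of the array's design is not named.

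Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend and robust off), with 1 mean per age and all 20 arrays in 1 fit (15 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. There were 8 comparisons of 2 ages and an F test over all ages. The main comparisons are 4 against 1 month, 10 against 4 months and 10 against 1 month. Of the 31 gene lists fixed before the data were examined, 29 had at least 3 tested genes. The red blood cell list (2 tested genes of 11) and the sex-linked list (2 of 5) were too small to test. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 29 lists of a comparison, and again with an estimated correlation and with fry. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. With an estimated correlation 5 lists were called for 2 months against 1 month, 2 for 6 months against 1 month and 0 for each of the others, and fry called 13, 16, 14, 21, 6, 0, 11 and 18 lists for 2, 4, 6 and 10 months against 1 month, 4 against 2, 6 against 4, 10 against 6 and 10 against 4 months. Counts of list members past the threshold use the adjustment over all genes tested, and the count adjusted over the list alone stands beside them.

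Named genes follow a rule set before the data were examined: the 12 largest rises and 12 largest falls among called genes whose 2 groups of 4 arrays did not overlap in the main comparisons, 3 and 3 in the others, up to 4 members of each list with the largest change (called genes first), and in any case a fixed set that includes Nrl, Nr2e3, Opn1sw, Opn1mw, Gnat2, Arr3, Pde6c, Gfap and Xist. Predicted genes and olfactory or vomeronasal receptors were skipped in the ranking. Kdm6a and Eif2s3x, named by the same rule, are X-linked.

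The alternatives were the mean of the probe sets or the brightest probe set in place of median polish, no filter or a filter of 50% on dim genes, median centring or quantile normalization, array weights, trend and robust eBayes, a replicate block, fits on the 8 arrays of 2 ages, a minimum change of 1.5-fold, and leaving out each array in turn. Covariates for the Y-linked level, the pigment epithelium level and the spread of each array, and the removal of 2 pairs of arrays, were added after seeing the data. The steps were tested on simulated data made from the real means and spreads with 200 changed genes. For 4 against 1 month, in a fit of 11852 genes, changes of 0.3, 0.6 and 1.2 on the log2 scale were called for 59.7%, 92.5% and 93.9% of the changed genes, with 7 of the 11652 unchanged genes called. For 6 against 4 months, where none of the measured genes was called, the simulated changes of 0.3 and 0.6 were called for 46.3% and 85.1% of the genes in a fit of the same size. In that simulation 67 genes changed by 0.6 and 66 by 1.2 at the same time, which eases the adjusted threshold for the smaller changes. With few changed genes the share called would be lower, so these shares do not show how complete the count of 0 is. The simulated genes were independent of each other, so the list tests were not tested there for correlated genes. Figures were drawn with matplotlib 3.10.9.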

Results

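Gene expression was measured in retinas of Nrl knockout mice at 5 ages after birth, 1, 2, 4, 6 and 10 months, with 4 mice per age and 1 array per mouse. Nrl encodes the transcription factor that directs photoreceptor precursors to the rod fate, and retinas that lack it form cone-like photoreceptors in place of rods. The title of the series speaks of cones preserved after a rapid but passing degeneration and remodeling, so the ages were compared to ask what changed early and what changed back later. All mice were knockouts. Without wild-type retinas of the same ages, changes due to the loss of Nrl cannot be told apart from normal maturation or ageing. Both retinas of a mouse made up a sample. The 20 arrays gave log2 levels for 15803 genes, and the 11852 genes left after the dimmest 25% were tested. All changes below are log2 differences between group means with their standard errors, n = 4 mice per age, and adjusted p-values come from limma with Benjamini-Hochberg adjustment. Each array measured RNA of the retina as a whole. A changed list mean therefore does not tell a change within cells from a changed share of a cell type.

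Nrl itself measured, over the arrays, from 5.97 to 6.53, where the limit for testing was 5.61. No wild-type array was analysed here, and the sources used here do not say whether its probe sets lie in the deleted part, so this level does not check the genotype. The rod gene Nr2e3 was among the dim genes and was not tested. Opn1sw, the gene of the short-wavelength cone opsin, measured 13.68 ± 0.03 (SD, n = 4) at 1 month and 13.58 ± 0.07 at 10 months. Xist was not analysed here. The array of 4 months replicate 4 stood apart from the rest, with a mean correlation of 0.960 with the other arrays. The Y-linked genes Eif2s3y and Kdm5d were high in all arrays of 1, 4 and 6 months and low in all 4 arrays of 2 months and in replicates 2 and 3 of 10 months. Eif2s3y, for example, was between 3.85 and 4.07 in the 2 month arrays and between 8.21 and 8.85 in the 1 month arrays. The labels give no sex for the mice. As no age but 10 months holds arrays of both kinds, 2 against 1 month and 4 against 2 months compare Y-linked levels along with ages.

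**Figure D1:**
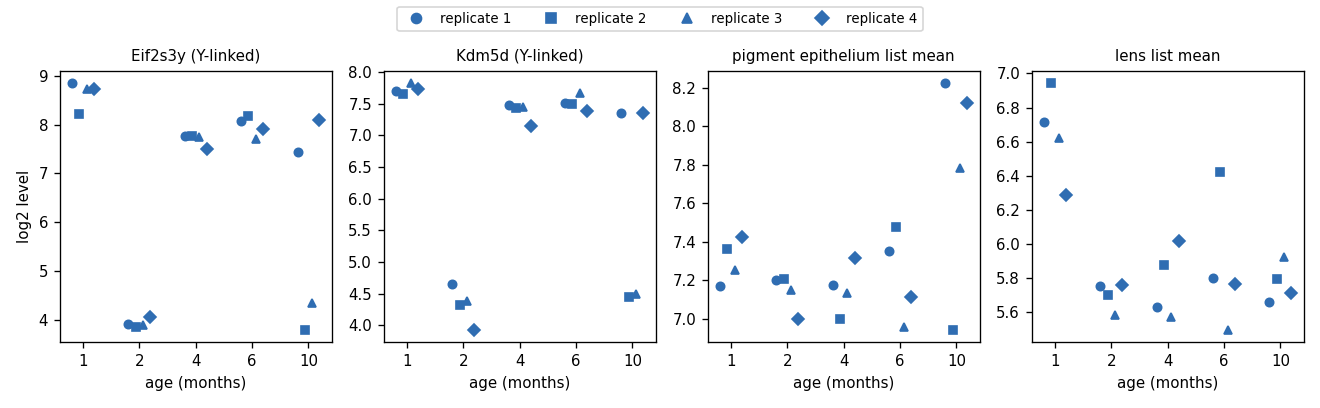
Log2 level per array (vertical axis) at each age in months (horizontal axis, ages evenly spaced) for Y-linked genes and the means of the pigment epithelium and lens lists, each point 1 array and each shape 1 replicate number. The 2 month arrays and replicates 2 and 3 of 10 months lie low in both Y-linked genes, and 3 of the 4 arrays of 10 months lie at 7.79 or more in the pigment epithelium list.

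Across the 5 ages, 4549 of the 11852 genes differed at any age by the moderated F test (2417 with the brightest probe set). The steps between neighbouring ages were unequal. Against 1 month, 1010 genes were called at 2 months (391 higher, 619 lower). Between 2 and 4 months 15 genes were called (9 higher, 6 lower), and 959 had an unadjusted p under 0.05. Between 4 and 6 months limma called 0 genes, with 530 at an unadjusted p under 0.05 and a smallest adjusted p of 0.895. Between 6 and 10 months 2404 genes were called (1015 higher, 1389 lower). No label or file gives a batch or date, so a difference in handling between ages and age itself cannot be told apart.

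**Figure D2:**
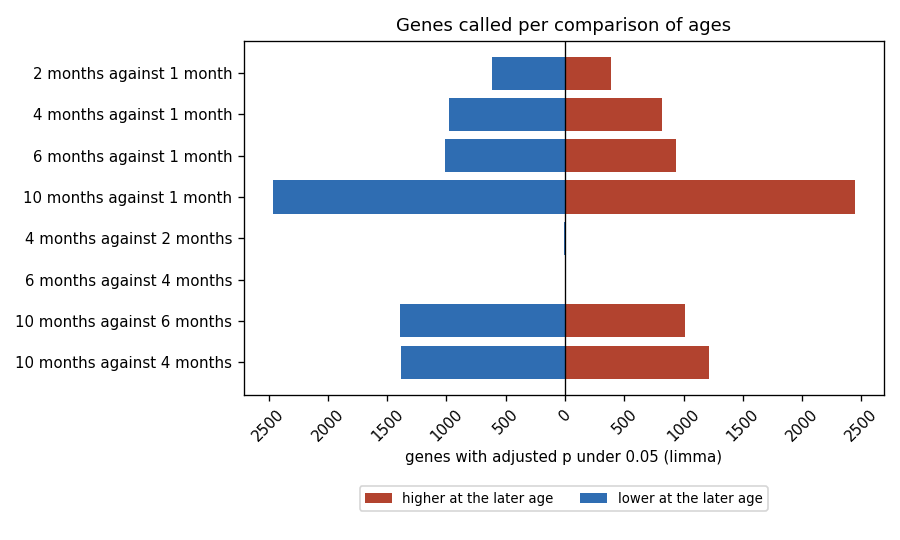
Number of genes past an adjusted p of 0.05 (horizontal axis) for each comparison of ages (vertical axis), genes higher at the later age to the right and lower to the left. The bars reach 2444 and 2463 genes for 10 months against 1 month, and none were called for 6 months against 4 months.

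At 2 months, genes of immune cells and glia were already higher than at 1 month. The 2 ages also differ in Y-linked level, so sex and age cannot be told apart within this comparison. In the microglia and macrophage list 8 of its 22 tested members rose (10 when adjusted over the list alone), and in the complement list 8 of its 10 tested members rose (8 when adjusted over the list alone). Both calls held with an estimated correlation (adjusted p = 0.00596 for each list). The gliosis list, with 10 of 21 members higher, the unfolded protein response list, with 8 of 18, and the Muller glia list, with 6 of 16, also held (adjusted p = 0.0181, 0.0181 and 0.0483 with an estimated correlation). Antigen presentation, interferon, oxidative stress, lens and immediate early lists were called at the preset correlation alone, with adjusted p between 0.0569 and 0.284 with an estimated correlation. Of 35 splits of these 8 arrays, 11, the real one included, called at least 10 lists at the preset correlation. The complement, gliosis, unfolded protein response and Muller glia means were 0.59, 0.41, 0.25 and 0.20 above 1 month at 2 months. At 4 months, high in Y-linked genes like 1 month, they were 0.54, 0.39, 0.18 and 0.27. The microglia mean was 0.32 at 2 and 0.19 at 4 months. Among genes whose 2 groups of arrays did not overlap, predicted genes left out, the largest rises were Ifit1, an interferon-induced gene (1.55 ± 0.38 (SE), adjusted p = 0.0152), the chemokine gene Cxcl13 (1.39 ± 0.21) and the metallothionein gene Mt2 (1.38 ± 0.22). The largest falls were the Y-linked Eif2s3y and Kdm5d (-4.69 ± 0.62 and -3.41 ± 0.49) and the lens crystallin gene Cryaa (-2.73 ± 0.49). The count of 1010 genes was 625, 616, 653 and 530 without replicate 2 of 1 month or replicates 2, 3 or 4 of 2 months, and 125 with the Y-linked level as a covariate, a fit chosen after seeing the data in which the calls of Ifit1 and Cryaa were lost as well. In the same fit the immediate early list was no longer called (mean change -0.26 without and -0.27 with the covariate, adjusted p = 0.148). There the mean changes of the oxidative stress, interferon and Muller glia lists went from 0.21, 0.46 and 0.20 to 0.47, 0.71 and 0.31, all 3 still called. The 1 and 2 month arrays do not overlap in the Y-linked genes, so that fit can hardly part the covariate from the comparison. Its slope rests mainly on the 10 month arrays (SD of Eif2s3y 2.16 there, 0.29 at 1 month and 0.09 at 2 months). The count of 125 therefore does not show how many calls are due to sex. The call of Ifit1, which rested on 1 probe set, was also lost without replicate 2 of 1 month or replicate 4 of 2 months (adjusted p up to 0.0569), and the count of genes was 344 with the brightest probe set and 2367 with array weights.

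The comparison of 4 months with 1 month covers the early period. It called 1795 genes, 819 higher and 976 lower at 4 months, of which 170 changed at least 1.5-fold. Complement and gliosis genes rose. C4b, a component of the classical complement pathway, rose from 8.56 ± 0.11 (SD, n = 4) to 9.90 ± 0.20, a change of 1.34 ± 0.12 (SE), adjusted p = 1.15e-06. The complement inhibitor genes Cd59a and Serping1 rose by 1.22 ± 0.15 and 0.90 ± 0.12. In the complement list 6 of its 10 tested members rose (6 when adjusted over the list alone) (camera adjusted p = 1.49e-05, adjusted p = 0.0677 with an estimated correlation). In the gliosis list 7 of its 21 tested members rose (10 when adjusted over the list alone) (camera adjusted p = 1.43e-05, adjusted p = 0.0842 with an estimated correlation). They were led by Mt2 (1.53 ± 0.22), the protease inhibitor gene Serpina3n (1.07 ± 0.17), A2m (0.94 ± 0.18) and the growth factor gene Fgf2 (0.76 ± 0.12). Gfap, the intermediate filament gene of reactive glia, did not pass (0.05 ± 0.13 (SE), adjusted p = 0.844).

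Microglia genes were higher as well. In that list 5 of its 22 tested members rose (6 when adjusted over the list alone), among them the protease gene Ctss and the integrin gene Itgam (0.55 ± 0.11 and 0.41 ± 0.08) (camera adjusted p = 0.000773, adjusted p = 0.115 with an estimated correlation). In the interferon list 5 of its 17 tested members rose (7 when adjusted over the list alone), with log2 changes of Ifit1 (1.52) and Oasl2 (0.74) (camera adjusted p = 0.000386, adjusted p = 0.343 with an estimated correlation). In the antigen presentation list 4 of its 13 tested members rose (4 when adjusted over the list alone), including B2m (0.57 ± 0.10) and the immunoproteasome gene Psmb8 (0.55 ± 0.11) (camera adjusted p = 0.000386, adjusted p = 0.161 with an estimated correlation). 

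Genes of Muller glia, the radial glia of the retina, rose. In the Muller glia list 10 of its 16 tested members rose (13 when adjusted over the list alone) (camera adjusted p = 2.99e-08, adjusted p = 0.0677 with an estimated correlation). These included the water channel gene Aqp4 (0.53 ± 0.09), the carbonic anhydrase gene Car14 (0.47 ± 0.07), Apoe (0.46 ± 0.07) and Hes1 (0.44 ± 0.07). In the bipolar list 6 of its 17 tested members rose (8 when adjusted over the list alone) and 2 fell, with Car8 at 0.63 ± 0.05 (camera adjusted p = 0.00204, adjusted p = 0.0842 with an estimated correlation). In the oxidative stress list 4 of its 23 tested members rose (4 when adjusted over the list alone), with Prdx6 at 0.60 ± 0.07 (camera adjusted p = 0.0476, adjusted p = 0.467 with an estimated correlation). In the unfolded protein response list 6 of its 18 tested members rose (6 when adjusted over the list alone), including the chaperone gene Hspa5 (0.44 ± 0.09) (camera adjusted p = 0.00166, adjusted p = 0.177 with an estimated correlation). The oxidative stress list had a mean change of 0.14, and its call was lost without replicates 1 or 3 of 1 month or replicates 1, 2 or 3 of 4 months (0.13 to 0.14, adjusted p from 0.0562 to 0.138).

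Some photoreceptor genes were lower, while the rod gene and photoreceptor synapse lists did not pass (camera adjusted p = 0.733 and 0.293). Within the rod gene list Pde6b went from 9.08 at 1 month to 8.39 at 4 months and Esrrb from 7.47 to 8.65, changes that cancel in a list mean. In the list of genes shared by rods and cones 6 of its 27 tested members fell (8 when adjusted over the list alone) and none rose. They included the cilium gene Rpgrip1 (-0.82 ± 0.08), Nxnl2 (-0.69 ± 0.07) and the matrix proteoglycan gene Impg1 (-0.59 ± 0.13) (camera adjusted p = 6.18e-05, adjusted p = 0.177 with an estimated correlation). In the cone list 3 of its 16 tested members fell (3 when adjusted over the list alone) and 1 rose, with cone arrestin Arr3 at -0.27 ± 0.07 and Thrb at 0.38 ± 0.06 (camera adjusted p = 0.0281, adjusted p = 0.369 with an estimated correlation). The cone list had a mean change of -0.08, and its call was lost without replicates 1 or 3 of 1 month or replicate 4 of 4 months (-0.08 to -0.06, adjusted p from 0.0523 to 0.0996), and with the spread of each array as a covariate, chosen after seeing the data (-0.06, adjusted p = 0.161). Opn1sw (-0.04 ± 0.05), Opn1mw (-0.09 ± 0.06), Gnat2 (-0.01 ± 0.05) and Pde6c (-0.15 ± 0.06) did not pass the threshold. Their mean levels lie at percentiles 100, 99.2, 99.96 and 99.87 of all genes. Whether signal still follows RNA at the top of the range was not tested, so these values do not show stable RNA. In the blood vessel list 7 of its 17 tested members fell (9 when adjusted over the list alone) (camera adjusted p = 0.00204, adjusted p = 0.177 with an estimated correlation). Among them were the endothelial tight junction gene Cldn5 (-0.94 ± 0.21) and the receptor gene Tek (-0.62 ± 0.09), while Flt1 rose (0.56 ± 0.08). In the immediate early list 5 of its 13 tested members fell (8 when adjusted over the list alone), with Npas4 at -0.70 ± 0.20 and Egr1 at -0.55 ± 0.13 (camera adjusted p = 0.00383, adjusted p = 0.284 with an estimated correlation). In the lens list 3 of its 10 tested members fell (4 when adjusted over the list alone), led by Cryaa (-2.54 ± 0.49) (camera adjusted p = 0.00261, adjusted p = 0.343 with an estimated correlation). The mean of the lens list lay between 6.29 and 6.94 in the arrays of 1 month and at 6.42 in replicate 2 of 6 months, and at 6.02 or less in all other arrays. This list was set as a check for other tissue. Lens carried over with the 1 month retinas was not tested and cannot be told apart from a retinal change. The same holds for Cryaa and Crygs in the comparisons with 1 month.

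Among genes whose groups did not overlap, the largest rises at 4 months were Hs6st2, a heparan sulfate sulfotransferase gene (1.62 ± 0.07 (SE), adjusted p = 3.91e-11), Fbxw21 (1.54 ± 0.17), Mt2, Shisal2b (1.38 ± 0.11), C4b, Cd59a, the nuclear receptor gene Esrrb (1.18 ± 0.08) and Tc2n (1.14 ± 0.14). They were followed by the endothelin receptor gene Ednrb (1.12 ± 0.28), Serpina3n, the sodium channel gene Scn7a (1.04 ± 0.12) and Arhgap15 (1.01 ± 0.17). The largest falls were Cryaa, the melatonin receptor gene Mtnr1a (-1.36 ± 0.19 (SE), adjusted p = 0.000117), Pdzph1 (-1.10 ± 0.14) and the splicing factor gene Srsf5 (-1.10 ± 0.13). After them came Crygs, Rsrp1, Slco1a4, Snhg11, Rps13, Pnpla3, Cldn5 and Glmn, with log2 changes from -1.08 to -0.94. The calls of Rps13, which rested on 1 probe set, and of Nr4a1 were lost in 5 and 6 of the 8 fits that left out 1 array, those of Npas4 and Crygs in 4 and 3 (adjusted p up to 0.114, 0.0999, 0.0741 and 0.108). With the brightest probe set in place of median polish the calls of Ednrb, Pdzph1, Crygs, Aqp4, A2m and Itgam were lost, and the count was 840, against 1052 with only the 8 arrays of both ages and 3027 with array weights.

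**Figure D3:**
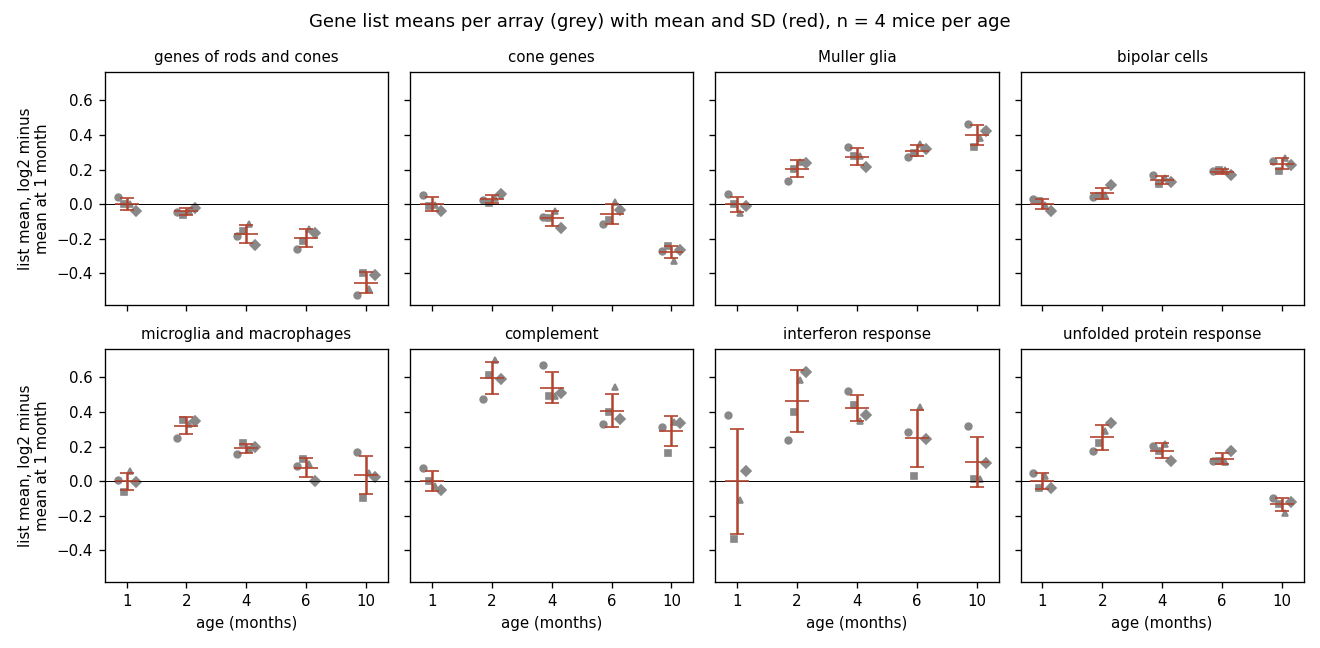
Mean log2 level of 8 gene lists minus their mean at 1 month (vertical axis) against age in months (horizontal axis, ages evenly spaced), with grey points for single arrays (circle, square, triangle and diamond for replicates 1 to 4) and red bars for the mean and SD of 4 mice. The complement list mean was 0.59 above 1 month at 2 months and 0.29 at 10 months, while the Muller glia list reached 0.40 at 10 months.

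By 6 months the number of genes that differed from 1 month was close to that at 4 months, 1945 (937 higher, 1008 lower). Hs6st2 (1.71 ± 0.07), Fbxw21 (1.74 ± 0.17) and Ednrb had the largest rises among genes whose groups did not overlap, and Pdzph1 (-1.60 ± 0.14), Mtnr1a (-1.53 ± 0.19) and Pclaf (-1.39 ± 0.32) the largest falls. The Muller glia and bipolar lists rose with both correlations, with 12 of 16 and 10 of 17 members higher (adjusted p = 0.0434 for each list with an estimated correlation). The gliosis, complement, oxidative stress and unfolded protein response lists were called higher, and the lists of rods and cones, lens, blood vessels and immediate early genes lower, at the preset correlation alone (adjusted p between 0.163 and 0.503 with an estimated correlation). The mean change of the lens list was -0.48, and its call was lost without replicate 3 of 6 months (-0.35, adjusted p = 0.0959). That of the unfolded protein response list was 0.13, and its call was lost without replicates 2 or 4 of 1 month or replicate 4 of 6 months (0.11 to 0.12, adjusted p from 0.0505 to 0.0619). The microglia list did not pass (camera adjusted p = 0.193, adjusted p = 0.556 with an estimated correlation). The count of genes was 954 with the brightest probe set, in which the call of Pdzph1 was lost, and 2968 with array weights.

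Among the 15 genes called between 2 and 4 months, 4 of the 6 with the largest changes and separate groups lie on the sex chromosomes. Eif2s3y and Kdm5d were higher at 4 months (3.76 ± 0.62 and 3.06 ± 0.49), and the X-linked genes Kdm6a and Eif2s3x, which escape X inactivation, were lower (-0.76 ± 0.13 and -0.63 ± 0.10). Shisal2b rose (0.66 ± 0.11) and Pde6b, a rod phosphodiesterase gene, fell (-0.59 ± 0.11). The count of 15 was 7, 1, 1 and 2 without replicates 1 to 4 of 2 months, 7 without replicate 2 of 4 months and 7 with the Y-linked level as a covariate, a fit chosen after seeing the data. As the 2 and 4 month arrays do not overlap in the Y-linked genes, that fit can hardly part sex from age. The calls of all 6 genes were lost in at least 3 of the 8 fits that left out 1 array. Of the lists, 10 were called at the preset correlation and 0 with an estimated one (adjusted p between 0.0555 and 0.352), and between 4 and 6 months 9 were called at the preset correlation (4 without replicate 1 of 4 months) and 0 with an estimated one (adjusted p between 0.294 and 0.571).

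From 4 to 10 months, the late period, 2597 genes changed, 1216 higher and 1381 lower, with 184 at least 1.5-fold. The list of genes shared by rods and cones and the cone list were lower, while the rod gene and photoreceptor synapse lists did not pass (camera adjusted p = 0.946 and 0.28). In the list shared by rods and cones 14 of its 27 tested members fell (15 when adjusted over the list alone), none rose, and Kcnv2 (-0.84 ± 0.08), Nxnl2 (-0.78 ± 0.07) and the retinol dehydrogenase gene Rdh12 (-0.71 ± 0.08) fell most (camera adjusted p = 4.33e-09, adjusted p = 0.131 with an estimated correlation). In the cone list 7 of its 16 tested members fell (7 when adjusted over the list alone), led by the channel subunit gene Cnga3 (-0.91 ± 0.07 (SE), adjusted p = 2.21e-07), with Opn1mw at -0.36 ± 0.06 and Arr3 at -0.30 ± 0.07 (camera adjusted p = 0.00111, adjusted p = 0.182 with an estimated correlation). Gnat2 (-0.01 ± 0.05), Opn1sw (-0.06 ± 0.05) and Pde6c (0.01 ± 0.06) did not pass, at levels where it was not tested whether signal still follows RNA.

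The microglia, complement and interferon lists were lower at 10 months than at 4 months, while the antigen presentation and lymphocyte lists did not pass (camera adjusted p = 0.946 and 0.943). In the microglia list 7 of its 22 tested members fell (9 when adjusted over the list alone) (camera adjusted p = 0.0063, adjusted p = 0.182 with an estimated correlation). Members that fell were Ctss (-0.58), Ly86 (-0.57) and Itgam (-0.53). In the complement list 5 of its 10 tested members fell (5 when adjusted over the list alone), with Serping1 at -0.61 ± 0.12 and C4b at -0.53 ± 0.12 (camera adjusted p = 0.0142, adjusted p = 0.222 with an estimated correlation). Without the 2 arrays of 10 months low in Y-linked genes, a fit chosen after seeing the data, the complement list was no longer called (mean change -0.25 with all arrays, -0.21 there, adjusted p = 0.0576). The mean change of the microglia list, -0.15 with all arrays, was -0.09 in that fit, -0.09 with the Y-linked covariate and -0.23 with the pigment epithelium covariate (adjusted p = 0.0378, 0.0373 and 0.000329). With the Y-linked covariate the complement list was not called either (mean change -0.21, adjusted p = 0.054). In the interferon list 4 of its 17 tested members fell (4 when adjusted over the list alone), with Oasl2 (-0.63), Stat2 (-0.63) and Irf9 (-0.54) (camera adjusted p = 0.00121, adjusted p = 0.313 with an estimated correlation). The unfolded protein response list was lower too: 8 of its 18 tested members fell (8 when adjusted over the list alone) (camera adjusted p = 2.81e-06, adjusted p = 0.131 with an estimated correlation). Creld2 changed by -0.98 ± 0.05 (SE), adjusted p = 4.23e-09, Pdia4 by -0.74 ± 0.07 and Hspa5 by -0.70 ± 0.09.

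Other groups rose from 4 to 10 months. In the immediate early list 7 of its 13 tested members rose (9 when adjusted over the list alone), including Nr4a1 (0.97), Egr1 (0.94) and Fos (0.93) (camera adjusted p = 0.000123, adjusted p = 0.182 with an estimated correlation). In the circadian clock list 6 of its 14 tested members rose (7 when adjusted over the list alone) and 1 fell, with the period gene Per1 at 0.78 ± 0.11 (camera adjusted p = 0.00116, adjusted p = 0.156 with an estimated correlation). In the ganglion cell list 5 of its 14 tested members rose (5 when adjusted over the list alone) (camera adjusted p = 0.00221, adjusted p = 0.182 with an estimated correlation). Muller glia had a rise in 4 of 16 genes (4 when adjusted over the list alone; camera adjusted p = 0.0142, adjusted p = 0.313 with an estimated correlation). In the cholesterol synthesis list 5 of its 14 tested members rose (5 when adjusted over the list alone), with Insig1 at 0.56 ± 0.07 (camera adjusted p = 0.0157, adjusted p = 0.182 with an estimated correlation). In the oxidative stress list 6 of its 23 tested members rose (10 when adjusted over the list alone), with the extracellular glutathione peroxidase gene Gpx3 at 2.39 ± 0.75 (camera adjusted p = 0.0112, adjusted p = 0.313 with an estimated correlation). In the pigment epithelium list 1 of its 13 tested members rose (10 when adjusted over the list alone) (camera adjusted p = 0.00277, adjusted p = 0.34 with an estimated correlation). The pigment cell genes Dct (1.49 ± 0.60) and Tyrp1 (1.18 ± 0.44) did not pass. The mean of this list at 10 months was 8.22, 6.94, 7.79 and 8.12 in replicates 1 to 4, and no array of another age exceeded 7.48. The mean changes of the Muller glia and oxidative stress lists were 0.12 and 0.27. The call of the first was lost without replicate 4 of 4 months or replicate 1 of 10 months (0.10, adjusted p from 0.063 to 0.076), and that of the second without replicate 4 of 4 months (0.24, adjusted p = 0.076).

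The largest rises from 4 to 10 months among genes whose groups did not overlap were the enkephalin precursor gene Penk (2.48 ± 0.61 (SE), adjusted p = 0.00709), Crhbp (1.38 ± 0.35), Mt2 (1.34 ± 0.22) and the cell cycle inhibitor gene Cdkn1a (1.32 ± 0.17). Next were Fbn1 (1.28 ± 0.28), the GABA transporter gene Slc6a13 (1.07 ± 0.25), Id2 (1.02 ± 0.16), Nr4a1, Coq10b, the cold-inducible gene Cirbp (0.95 ± 0.06), Egr1 and Fos. Penk was at 7.96 in replicate 2 of 10 months and at 10.95 or more in the other 3. It also varied between mice at 2 and 6 months (8.57 ± 1.29 and 8.51 ± 0.78, SD, n = 4) and less at 1 and 4 months (8.06 ± 0.12 and 7.76 ± 0.19). The largest falls were Senp8, Creld2, Cep97 (-0.95 ± 0.09), Ciao1 and Cnga3. Further falls were those of Chrnb4, Crp, Kcnv2, Serpina3n (-0.84 ± 0.17), Chordc1, H3c15 and Bmp15, the last with -0.82 ± 0.10. With the pigment epithelium level of each array as a covariate, a fit chosen after seeing the data, the count fell to 1055 and the calls of Penk, Crhbp, Fbn1, Slc6a13, Gpx3, C4b and Arr3 were lost. So were those of the Muller glia list (mean change 0.12 with all arrays, 0.10 there, camera adjusted p = 0.0727) and the oxidative stress list (0.27 and 0.15, camera adjusted p = 0.0727). The pigment epithelium list was not called either (camera adjusted p = 0.882), but the covariate is the mean of that same list, so its loss follows by construction. With the brightest probe set the count fell to 1075 (1101 with only the 8 arrays of both ages), Fbn1 and Cep97 changed sign, and the calls of Crhbp, Slc6a13, Coq10b, Chordc1, Ly86 and Gpx3 were lost, the last also in 5 of the 8 fits that left out 1 array (adjusted p up to 0.0902).

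Between 6 and 10 months Cdkn1a, Mt2 and Egr1 rose most among genes whose groups did not overlap (1.57, 1.47 and 1.13), and Kdm5d, Rbm12b1 and Cep97 fell most (-1.60, -1.48 and -1.06). In that comparison 10 lists were called, none of them with an estimated correlation (adjusted p between 0.117 and 0.572), and 5 at the preset correlation without replicate 1 of 10 months. The call of Kdm5d was lost in 3 of the 8 fits that left out 1 array (adjusted p up to 0.0971), and Cep97 changed sign with the brightest probe set. The count of genes was 988 with that probe set and 1290 with the pigment epithelium covariate.

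**Figure D4:**
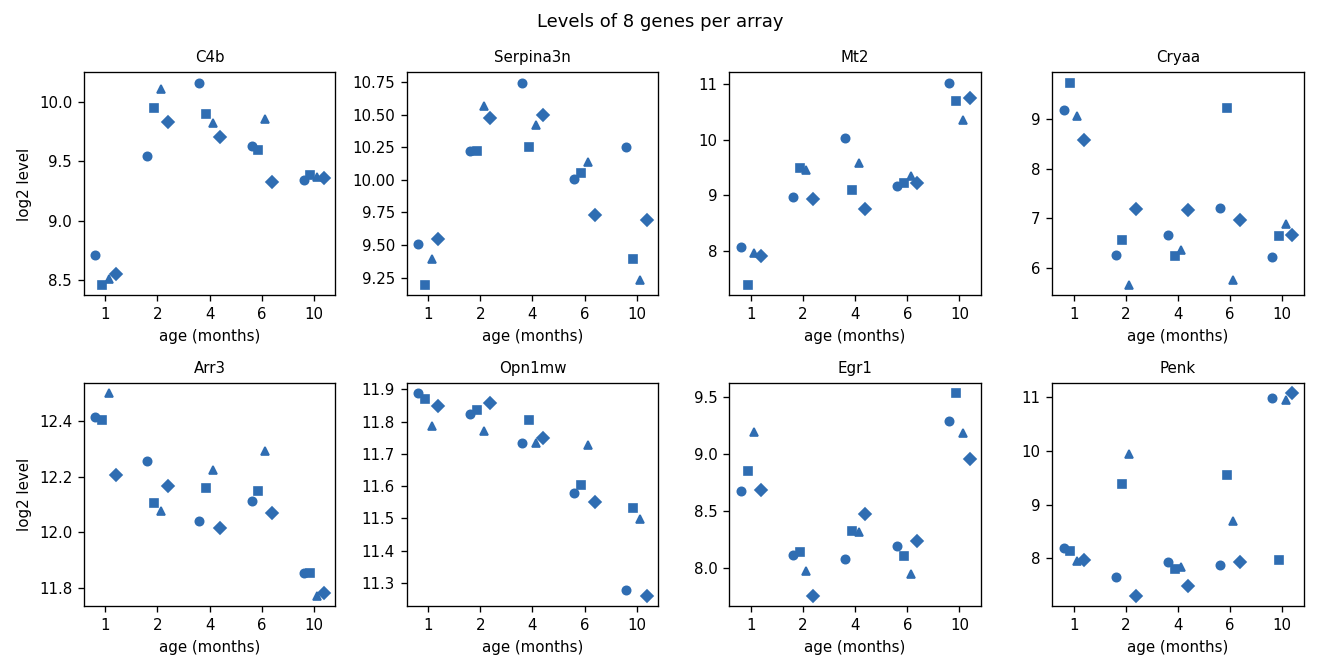
Log2 level (vertical axis) of 8 genes in each of the 20 arrays against age in months (horizontal axis, ages evenly spaced), each point 1 array, with circle, square, triangle and diamond for replicates 1 to 4. C4b is highest at 2 and 4 months, Arr3 lowest at 10 months, and Penk at 10 months splits into 3 arrays at 10.95 or more and 1 at 7.96.

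Over the whole series, from 1 to 10 months, 4907 genes changed, 2444 higher and 2463 lower, with 675 at least 1.5-fold. Muller glia and gliosis genes were higher. In the Muller glia list 14 of its 16 tested members rose (14 when adjusted over the list alone), with Car14 at 0.78 ± 0.07 and Hes1 at 0.75 ± 0.07 (camera adjusted p = 1.08e-06, adjusted p = 0.101 with an estimated correlation). In the gliosis list 12 of its 21 tested members rose (14 when adjusted over the list alone) (camera adjusted p = 0.00104, adjusted p = 0.2 with an estimated correlation). Mt2 rose by 2.88 ± 0.22 (SE), adjusted p = 2.01e-08, Mt1 by 1.42 ± 0.10 and Lcn2 by 1.01 ± 0.16. Gfap did not pass (-0.29 ± 0.13). In the oxidative stress list 13 of its 23 tested members rose (14 when adjusted over the list alone), with the cystine transporter gene Slc7a11 at 1.44 ± 0.21 (camera adjusted p = 0.00459, adjusted p = 0.379 with an estimated correlation). The mean of this list above 1 month was 0.56, 0.21, 0.40 and 0.48 in replicates 1 to 4 of 10 months, where that of the pigment epithelium list was 0.93, -0.41, 0.51 and 0.88. Gpx3 and Niban1 were likewise lowest in replicate 2, at 7.36 and 7.08, with an SD over the 4 arrays of 1.496 and 0.90. The SD of Gpx3 was also large at 2 and 6 months (1.68 and 1.33), against 0.19 at 1 month and 0.19 at 4 months. With the pigment epithelium covariate the calls of Gpx3 and Sod3 for 10 months against 1 month were lost and that of the list was not. In the antigen presentation list 8 of its 13 tested members rose (8 when adjusted over the list alone) (camera adjusted p = 0.0241, adjusted p = 0.379 with an estimated correlation). Its mean change was 0.28, and its call was lost without replicate 2 of 1 month (0.24, adjusted p = 0.0543), and with the array spread covariate (0.23, adjusted p = 0.0524). In the bipolar list 10 of its 17 tested members rose (12 when adjusted over the list alone), with Vsx1 at 0.59 ± 0.08 (camera adjusted p = 0.00252, adjusted p = 0.101 with an estimated correlation). In the ganglion cell list 7 of its 14 tested members rose (7 when adjusted over the list alone) (camera adjusted p = 0.033, adjusted p = 0.379 with an estimated correlation). Its mean change was 0.22, and its call was lost without replicate 1 of 10 months (0.20, adjusted p = 0.087). In the circadian clock list 8 of its 14 tested members rose (9 when adjusted over the list alone) (camera adjusted p = 0.00504, adjusted p = 0.2 with an estimated correlation). Camera called the lists of rod genes, retinoid cycle, horizontal cells, lymphocytes, glycolysis and cell cycle in no comparison. Fry, which does not compare a list with other genes, called the retinoid cycle, horizontal cell and cell cycle lists for 10 months against 1 month (fry adjusted p = 0.0337, 0.000434 and 0.000137). The retinoid cycle list was at 0.29, -0.12, 0.32 and 0.59 in replicates 1 to 4 of 10 months, low in replicate 2 like the pigment epithelium list. The microglia and interferon lists did not pass at 10 months against 1 month (camera adjusted p = 0.99 and 0.935, fry adjusted p = 0.753 and 0.898). The complement list did not pass with camera (camera adjusted p = 0.146, adjusted p = 0.515 with an estimated correlation) and did with fry (adjusted p = 0.00117). Of its 10 tested members 3 stayed higher than at 1 month and 0 were lower (3 and 0 when adjusted over the list alone). Its mean was 0.31, 0.16, 0.34 and 0.34 in the 10 month arrays and 0.08, 0.00, -0.03 and -0.05 in the 1 month arrays, with no overlap, and C4b was at 9.37 ± 0.02 (SD, n = 4).

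Of the photoreceptor lists, that of genes shared by rods and cones and the cone list fell from 1 to 10 months at the preset correlation. The rod gene list did not pass (mean change -0.05, camera adjusted p = 0.935, fry adjusted p = 0.473). Its members moved in opposite directions. Pde6b went from 9.08 ± 0.03 (SD, n = 4) at 1 month to 7.99 ± 0.24 at 10 months, and Esrrb from 7.47 ± 0.11 to 8.90 ± 0.19. Such changes cancel in a list mean, so the result does not show that rod genes were stable. The photoreceptor synapse list did not pass with camera (mean change -0.12, camera adjusted p = 0.146) and did with fry (adjusted p = 0.00854). In the list shared by rods and cones 21 of its 27 tested members fell (22 when adjusted over the list alone) and none rose, with the largest changes in Nxnl2 (-1.47 ± 0.07 (SE), adjusted p = 4.12e-11), Impg1 (-1.14 ± 0.13), Rpgrip1 (-0.94 ± 0.08) and Kcnv2 (-0.94 ± 0.08) (camera adjusted p = 1.15e-10, adjusted p = 0.101 with an estimated correlation). In the cone list 9 of its 16 tested members fell (11 when adjusted over the list alone) and 1 rose, with Cnga3 at -0.93 ± 0.07, Arr3 at -0.57 ± 0.07 and Opn1mw at -0.46 ± 0.06 (camera adjusted p = 0.0005, adjusted p = 0.2 with an estimated correlation). Opn1sw (-0.10 ± 0.05 (SE), adjusted p = 0.0866), Gnat2 (-0.03 ± 0.05) and Pde6c (-0.14 ± 0.06) did not pass. These genes lie at the top of the measured range, so, as for 4 against 1 month, the values do not show stable RNA. In the blood vessel list 7 of its 17 tested members fell (7 when adjusted over the list alone), with Cldn5 at -1.10 ± 0.21 and Rgs5 at -0.79 ± 0.10 (camera adjusted p = 0.0294, adjusted p = 0.379 with an estimated correlation). The mean change of the blood vessel list was -0.23, and its call was lost without replicate 4 of 1 month or replicates 2 or 4 of 10 months (-0.22 to -0.21, adjusted p from 0.0542 to 0.068), and with the Y-linked covariate (-0.21, adjusted p = 0.0516). The largest rises among genes whose groups did not overlap were Mt2, Gpx3 (2.83 ± 0.75), Hs6st2 (2.01 ± 0.07), Cdkn1a (1.76 ± 0.17), Fam107a, Fbxw21, Tc2n, Ednrb, Etnppl, Shisal2b, Niban1 and Slc7a11. The largest falls were Eif2s3y, Cryaa (-2.54 ± 0.49), Kdm5d, Pdzph1 (-1.79 ± 0.14), Mtnr1a (-1.72 ± 0.19), Srsf5 (-1.71 ± 0.13), Tnfsf12, Rbm12b1, Nxnl2, Crp, Moxd1 and Rps13. Of the 4 arrays of 10 months, 2 were low in Eif2s3y and Kdm5d and the other two were not.

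Genes that changed from 1 to 4 months and changed back from 4 to 10 months numbered 135, with 62 that rose and then fell and 73 that fell and then rose. The first group held 4 members of the complement list, 3 of the unfolded protein response list and 2 each of the gliosis, microglia and interferon lists, such as C4b, Serpina3n, Fgf2, Itgam and Hspa5. The second group held 3 immediate early genes, Egr1, Npas4 and Nr4a1, and the cold-inducible gene Cirbp. The 4 against 1 month calls of Nr4a1 and Npas4 were lost in 6 and 4 of the 8 fits that left out 1 array. That of Npas4 for 10 against 4 months was lost in 2 of 8 (limma adjusted p up to 0.0552). Both comparisons use the 4 month arrays, which alone makes their changes oppose. Yet independent lists of the same sizes would share 95.4 and 100.1 genes, more than the 62 and 73 found, and more genes went on in 1 direction, 192 up in both (84.0 for independent lists) and 249 down in both (113.7). The correlation of the 2 sets of changes across genes was 0.12, where simulated unchanged groups gave -0.50, and the covariance exceeded the simulated one by 0.0114. Genes are not independent replicates. With the 4 month arrays split into 2 and 2, a pair for each comparison, the count was 41.5 on average over the 6 splits (30 to 64). The count was 88 without replicate 2 of 4 months, 56 with the brightest probe set, 51 with the pigment epithelium covariate and 334 with array weights.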

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

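The tests of pigment epithelium, of the mixed 10 month group, of handling, of dilution and of a sex difference at 10 months were chosen only after the result was seen, while the splits of the arrays and the test of sex at 2 months were not. In each age of 4 arrays, a value was picked out where 1 array lay far from the other 3, by a gap that takes up most of the range of the 4 (Dixon's test at 95%). Chance alone picks about 1 in 20 groups. Of the 145 groups of list means 9 were picked (7.25 by chance), of the 760 groups of named genes 44 (38.0 by chance), and of the 10 groups of array measures 0. The array of 4 months replicate 4 held 11 of these, more than any other array. No explanation was tested for the single values.

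The list means that lay apart, as log2 difference from the mean of 1 month, were photoreceptor synapse at 0.076 (2 months replicate 4), horizontal cells at -0.061 (1 month replicate 3), amacrine cells at 0.11 (4 months replicate 1), complement at 0.67 (4 months replicate 1), complement at 0.16 (10 months replicate 2), retinal pigment epithelium at -0.31 (2 months replicate 4), unfolded protein response at 0.18 (6 months replicate 4), extracellular matrix at -0.16 (2 months replicate 4) and extracellular matrix at 0.015 (4 months replicate 4). Pdia4 10.04 lay apart in 1 month replicate 1. Rbpms 9.15 lay apart in 1 month replicate 2. Hs6st2 6.28, Fgf2 8.45, Slc7a11 5.78, Id2 6.85 and Ciao1 9.06 lay apart in 1 month replicate 3. B2m 9.23, Trib3 6.87 and Coq10b 8.46 lay apart in 2 months replicate 1. Hmox1 6.98 lay apart in 2 months replicate 3. Esrrb 8.42 and H2-Eb1 6.41 lay apart in 2 months replicate 4. Cxcl13 7.125, Cldn5 5.88 and Car14 10.13 lay apart in 4 months replicate 1. Pclaf 6.55 and Pcp2 9.70 lay apart in 4 months replicate 2. Eif2s3y 7.502, Kdm5d 7.155, Ctss 9.21, Nrl 6.535, Scgn 9.37, H2-Eb1 7.16, Eif2s3x 10.15, Coq10b 7.99, Chordc1 6.14 and Cyp51 8.03 lay apart in 4 months replicate 4. Pdzph1 6.725 and Tnfsf12 8.28 lay apart in 6 months replicate 1. Crygs 7.28, Fcgr3 6.08, H2-Eb1 6.40 and Dct 9.01 lay apart in 6 months replicate 2. Esrrb 8.58 lay apart in 6 months replicate 3. Kdm6a 8.14 lay apart in 6 months replicate 4. Fcgr3 5.785 and Asns 9.35 lay apart in 10 months replicate 1. Ifit1 5.14, Apoe 11.88, Sod3 6.26, Penk 7.96 and Slc6a13 6.635 lay apart in 10 months replicate 2. Glmn 8.19 lay apart in 10 months replicate 4.

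Splits of the arrays were used to ask whether chance gives as many genes. For 2, 4, 6 and 10 months against 1 month, for 4 against 2, 10 against 6 and 10 against 4 months, 1 of the 35 splits, the real one, gave as many genes, so chance can be excluded for each comparison taken alone, with no adjustment for the 8 comparisons. A share of 1 in 35 is the least that these splits can give. It speaks to chance alone and not to other structure of the samples. For 2 against 1 and 4 against 2 months the real split also parts the arrays by Y-linked level. The real counts were 1010, 1795, 1945, 4907, 15, 2404 and 2597, and the highest of the other splits 0, 254, 0, 1, 1, 41 and 1580. The 15 genes of 4 against 2 months are the least secure, at 7, 1, 1 and 2 without replicates 1 to 4 of 2 months and 7 without 4 months replicate 2. For 6 against 4 months the real count was 0 (highest other 1), so all 35 splits give at least as many by construction and nothing follows about chance. For genes differing at any age, 1 of 100 random regroupings gave as many (4549, highest other 2), so chance can be excluded. For genes that changed and changed back it was also 1 of 100 (135, highest other 1), but regroupings that call few genes leave few to share, so this does not test the overlap. Given the sizes of the real lists, independent lists would share 95.4 and 100.1 genes, more than the 62 and 73 found. The split with 1580 genes exchanges replicate 4 of 4 months and replicate 4 of 10 months, and the split with 254 exchanges replicate 4 of 1 month and replicate 4 of 4 months. Both point to a structure of the samples in which 4 months replicate 4 stands apart. In 10 against 4 months, 828 genes were called by the split that exchanges replicates 2 and 4 of 4 months and replicates 1 and 4 of 10 months, and so parts these 2 of 10 months from the 2 low in Y-linked genes. It also parts all 8 arrays by the spread of their values (SD 2.28 to 2.32 against 2.22 to 2.27). The 4 month arrays are all high in Y-linked genes, so that level does not part them. Neither was tested as the cause.

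The counts of lists are less secure. For 2, 4, 6 and 10 months against 1 month, 11, 2, 8 and 8 of the 35 splits gave as many lists as the real 10, 14, 10 and 10 (highest other 13, 15, 12 and 14), so chance cannot be excluded. Nor can it for 6 against 4 months (2 splits, real 9, highest other 9) and 10 against 6 months (6 splits, real 10, highest other 11). For 4 against 2 months (real 10, highest other 9) and 10 against 4 months (real 13, highest other 12), 1 split, the real one, gave as many, so chance can be excluded for each comparison taken alone, again with no adjustment for their number. But the margin is 1 list, both counts were 0 with an estimated correlation, and the 10 was 7 without 4 months replicate 1, so which lists are called is not secure.

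Many genes were called for 10 against 4 months and none for 6 against 4 months. With the pigment epithelium level of each array as a covariate, 40.0% of the calls kept their direction and their side of the threshold (1039 of 2597), the median size of the changes went from 0.293 with a median SE of 0.0695 to 0.269 with 0.0868, and calls ended as the SE grew by more than the changes shrank, so carried-over epithelium does not account for the whole pattern. Without the 2 arrays low in Y-linked genes, 69.0% were kept, with a median ratio of changes of 1.05, so the mixed group alone does not account for the whole pattern either. The arrays of 10 months left in that fit, replicates 1 and 4, had the highest pigment epithelium means (8.22 and 8.12). The mean change of that list was 1.07 there, against 0.64 with all arrays. Each explanation was tested singly, so a joint part of both stays open. The immediate early list rose by 0.463, but no date or batch is given, and another time of day, handling or batch at 10 months cannot be told apart from age. Age itself stays open as an untested explanation.

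The 2 month arrays were low in Y-linked genes and differed from 1 month in 1010 genes. If a difference in sex were the cause, genes called on 2 of the 1 month arrays would be near 0 for 4 against 1 month on the other 2, as both ages are high in Y-linked genes. Over the 6 splits the lowest ratio of the median changes was 1.02 and the highest 1.07, with at least 96.3% of the genes in the same direction, so sex does not account for the called genes as a set. Single genes are not covered by this test. The labels give no sex. The X-linked Eif2s3x and Kdm6a, which escape X inactivation, were at 11.03 ± 0.09 and 8.94 ± 0.01 at 2 months (SD, n = 4). Eif2s3x was at 10.31 ± 0.09, 10.39 ± 0.16 and 10.55 ± 0.10 at 1, 4 and 6 months. Kdm6a was at 8.23 ± 0.17, 8.18 ± 0.31 and 8.31 ± 0.11. With the Y-linked levels, this argues that the 2 month mice were female and those of 1, 4 and 6 months male. Whether labels were exchanged stays open, as does the sex of the 2 arrays of 10 months low in Y-linked genes. Age also stays open as an untested explanation.

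The list of genes shared by rods and cones and the microglia, complement and interferon lists were lower at 10 than at 4 months at the preset correlation. With an estimated correlation 0 lists were called (camera adjusted p from 0.131 to 0.34 for those lost). Dilution by tissue that lacks these genes would lower every retinal cell type alike, yet the ganglion, bipolar, amacrine and Muller genes differed by a mean of 0.122 where the list shared by rods and cones differed by -0.28 (exact permutation p = 0.0286, the smallest the design gives, two-sided). That list was picked because it was already lower in these same arrays. A small p follows largely from that choice, so it adds no support beyond the 2 values. The comparison covers the list shared by rods and cones alone, so dilution was not tested for the microglia, complement and interferon lists. The Muller glia call was lost with the pigment epithelium covariate, and whether other tissue adds to the Muller genes was not tested. Without the 2 arrays low in Y-linked genes the median change of the members was 0.797 of that with all arrays (-0.22), so sex does not account for the whole shift, though the call of the complement list was lost in that fit (mean change -0.25 with all arrays, -0.21 there, adjusted p = 0.0576) and the change of the microglia list went from -0.15 to -0.09 (adjusted p = 0.0378). That of the interferon list went from -0.31 to -0.21. For these 3 lists a part due to sex stays open. Age stays open as an untested explanation, and so does a difference in handling at 10 months.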

How the results depend on the processing

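The covariates and the removal of pairs of arrays were chosen after seeing the data; all other alternatives were chosen before. Of 245 results of named genes, 0 calls were lost with median centring, 6 with quantile normalization, 8 with array weights, 25 with 8 arrays, 20 with the Y-linked and 26 with the pigment epithelium covariate, and of 221 results 48 were lost with the brightest probe set. Counts that moved by over 1.5 times are given by alternative, with the comparison in months, and the cause was not tested except where fewer arrays or a stricter threshold set it. The brightest probe set gave 2417 (any age), 344 (2 against 1), 840 (4 against 1), 954 (6 against 1), 4 (4 against 2), 988 (10 against 6), 1075 (10 against 4), 56 (changed back), 6 (lists 4 against 2), 3 (lists 6 against 4) and 5 (lists 10 against 6). Array weights gave 2367 (2 against 1), 3027 (4 against 1), 2968 (6 against 1), 111 (4 against 2) and 334 (changed back). A minimum change of 1.5-fold, a stricter threshold, left 102 (2 against 1), 170 (4 against 1), 157 (6 against 1), 675 (10 against 1), 6 (4 against 2), 185 (10 against 6), 184 (10 against 4) and 7 (changed back). The Y-linked covariate gave 125 (2 against 1), 7 (4 against 2) and 5 (lists 4 against 2). The 2 month arrays do not overlap with those of 1 or 4 months in the Y-linked genes, so these counts cannot part sex from age. The covariate for array spread gave 1979 (2 against 1), 2721 (4 against 1), 2975 (6 against 1), 25 (4 against 2) and 311 (changed back). Fits on the 8 arrays of 2 ages, with fewer samples, gave 1052 (4 against 1), 5 (4 against 2), 1101 (10 against 4) and 6 (lists 10 against 6). Without a filter on dim genes the counts were 9 (4 against 2) and 1 (6 against 4). The pigment epithelium covariate gave 1290 (10 against 6), 1055 (10 against 4) and 51 (changed back). Camera with an estimated correlation gave 5 (lists 2 against 1), 0 (lists 4 against 1), 2 (lists 6 against 1), 0 (lists 10 against 1), 0 (lists 4 against 2), 0 (lists 6 against 4), 0 (lists 10 against 6) and 0 (lists 10 against 4). Leaving out the lowest 50% of genes gave 8 (lists 4 against 1). Fry, which does not compare a list with other genes, gave 21 (lists 10 against 1), 6 (lists 4 against 2) and 0 (lists 6 against 4). Quantile normalization gave 5 (lists 6 against 4). Without 1 array in turn, the ranges were 3975 to 5130 (any age), 530 to 1058 (2 against 1), 1342 to 1779 (4 against 1), 1351 to 1855 (6 against 1), 4288 to 4682 (10 against 1), 1 to 12 (4 against 2), 0 to 0 (6 against 4), 1851 to 2307 (10 against 6), 2059 to 2729 (10 against 4), 88 to 166 (changed back), 10 to 12 (lists 2 against 1), 12 to 14 (lists 4 against 1), 9 to 14 (lists 6 against 1), 9 to 11 (lists 10 against 1), 7 to 12 (lists 4 against 2), 4 to 10 (lists 6 against 4), 5 to 11 (lists 10 against 6) and 12 to 16 (lists 10 against 4). Counts for 2 against 1 were 625, 616, 653 and 530 without 1 month replicate 2 and 2 months replicates 2, 3 and 4. With a replicate block they were 4091 (any age), 830 (2 against 1), 1550 (4 against 1), 1633 (6 against 1), 4624 (10 against 1), 11 (4 against 2), 0 (6 against 4), 2110 (10 against 6), 2279 (10 against 4), 101 (changed back), 12 (lists 2 against 1), 13 (lists 4 against 1), 10 (lists 6 against 1), 10 (lists 10 against 1), 10 (lists 4 against 2), 8 (lists 6 against 4), 10 (lists 10 against 6) and 13 (lists 10 against 4). The replicate numbers did not pair the arrays (mean correlation -0.05 over 40 pairs). Log2 changes changed sign in 50 cases over 25 results, of which 37 were past the threshold in neither fit. Kdm5d (2 against 1) 0.12, Kdm5d (10 against 1) 0.16, Pou4f3 (10 against 1) -0.027, Gnat2 (10 against 1) 0.021, Eif2s3y (4 against 2) -0.085, Gnat2 (10 against 4) 0.021 and the list of Muller glia (4 against 2) -0.020 were the log2 changes under the Y-linked covariate. That covariate is the mean of Eif2s3y and Kdm5d, so the changes of these genes near 0 follow by construction. Mip (4 against 1) 0.12, Cdh5 (4 against 1) 0.096, Cep97 (10 against 6) 0.14, Fbn1 (10 against 4) -0.14, Cep97 (10 against 4) 0.13, Manf (10 against 4) 0.049 and Pde6c (10 against 4) -0.039 were the log2 changes with the brightest probe set. Gnat2 (4 against 1) 0.046, Opn1sw (10 against 4) 0 and Pde6c (10 against 4) -0.0096 were the log2 changes after quantile normalization. That step gives the brightest gene of each array the same value, and Opn1sw has the highest mean level, so its 0 carries no information. Gnat2 (4 against 1) 0.015 and Pde6c (10 against 4) -0.047 were the log2 changes under array weights. Gnat2 (4 against 1) 0.0081 and Opn1sw (4 against 1) 0.00067 were the log2 changes under the array spread covariate. Nrl (4 against 1) 0.046, Pcp2 (10 against 1) -0.14 and Gnat2 (10 against 4) 0.0098 were the log2 changes with the mean of the probe sets. Nrl (4 against 1) 0.0058 was the log2 change after median centring. Nrl (4 against 1) 0.013, Dct (10 against 4) -0.070, Tyrp1 (10 against 4) -0.058, Gnat2 (10 against 4) 0.0033, the list of retinal pigment epithelium (10 against 6) -0.027 and the list of retinal pigment epithelium (10 against 4) -0.011 were the log2 changes under the pigment epithelium covariate. As this covariate is the mean of that list, which holds Dct and Tyrp1, the values of the list follow by construction, and those of its members largely so. Gnat2 (10 against 1) 0.0079 and Gnat2 (10 against 4) 0.021 were the log2 changes without the 2 arrays of 10 months low in Y-linked genes. Gnat2 (10 against 4) 0.0017, Nrl (10 against 4) 0.0021 and Pde6c (10 against 4) -0.0053 were the log2 changes without the 2 arrays of lowest correlation. Without 1 array in turn the changes that crossed 0 ranged from -0.029 to 0.11 for Gfap (4 against 1), -0.033 to 0.015 for Gnat2 (4 against 1), -0.11 to 0.054 for Nrl (4 against 1), -0.055 to 0.0021 for Gnat2 (10 against 1), -0.041 to 0.0064 for Gnat2 (10 against 4), -0.12 to 0.026 for Nrl (10 against 4) and -0.037 to 0.042 for Pde6c (10 against 4). Signal over background limits the rest: genes under log2 5.61 were not tested.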

Other observations

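The fits with the pigment epithelium and Y-linked covariates were chosen after the data were seen, the other tests were not. Between 4 and 6 months limma called 0 genes and 530 had an unadjusted p under 0.05, and the list means were small. The mean change was -0.15 (camera adjusted p = 0.00018, adjusted p = 0.302 with an estimated correlation) for the gliosis list, -0.17 (camera adjusted p = 0.00018, adjusted p = 0.431 with an estimated correlation) for the interferon list and -0.09 (camera adjusted p = 0.0466, adjusted p = 0.325 with an estimated correlation) for the cell death list. For oxidative phosphorylation it was 0.08 (camera adjusted p = 0.0466, adjusted p = 0.571 with an estimated correlation). No member of these lists passed on its own. The interferon value was -0.10 without 6 months replicate 2 (adjusted p = 0.0102). The call of the cell death list was lost without replicates 1, 2 or 4 of 4 months or replicates 3 or 4 of 6 months (-0.12 to -0.03, adjusted p from 0.0568 to 0.362). That of oxidative phosphorylation was lost without replicates 1 or 4 of 4 months or replicates 3 or 4 of 6 months (0.02 to 0.09, adjusted p from 0.136 to 0.242). Without replicate 4 of 4 months alone, the array that stands apart, the 2 values were -0.03 and 0.02, so both rest in large part on this array.

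Between 2 and 4 months the photoreceptor synapse list had a mean change of -0.08 (camera adjusted p = 0.00306, adjusted p = 0.268 with an estimated correlation) and the amacrine cell list one of 0.08 (camera adjusted p = 0.00133, adjusted p = 0.143 with an estimated correlation), with 0 members of either past the threshold. The call of the first was lost without replicate 4 of 4 months (-0.05, adjusted p = 0.114) and that of the second without replicate 1 of 4 months (0.06, adjusted p = 0.0694). With the Y-linked covariate both were lost (-0.10 and 0.02, adjusted p = 0.159 and 0.803), in a fit that can hardly part the Y-linked level from these ages. Between 6 and 10 months, 4 of 17 extracellular matrix genes rose and 1 fell (4 and 1 when adjusted over the list alone), with a mean change of 0.19 (camera adjusted p = 0.0415, adjusted p = 0.287 with an estimated correlation). In replicates 1 to 4 of 10 months this list lay at 0.16, -0.08, 0.10 and 0.09 against 1 month, where the pigment epithelium list lay at 0.93, -0.41, 0.51 and 0.88, and replicate 2 lay within the 6 month values (-0.07, -0.07, -0.18 and -0.17). With the pigment epithelium covariate the change was 0.09 (adjusted p = 0.313) and the list was no longer called. The call was also lost without replicates 3 or 4 of 6 months or replicates 1 or 3 of 10 months (0.16 to 0.18, adjusted p from 0.0542 to 0.14). In the immediate early list 6 of its 13 tested members rose (9 when adjusted over the list alone) (camera adjusted p = 1.7e-05, adjusted p = 0.117 with an estimated correlation).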
